A study of Mus musculus with 4 samples.

How the data were processed

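The data were single-cell RNA counts of T cells sorted from mouse thymus, in 4 libraries, with 2 WT and 2 Ikzf4 cKO libraries. F1 and F2 in the library titles were taken as 2 batches. Per the file headers, the authors made raw UMI counts per gene and barcode with Cell Ranger 8.0.1. Per the labels the genome build was mm10, and Seurat was also named, without its version or role. The deposited matrices held 32285 genes. The filter that chose the deposited barcodes, the gate of the sort, the chemistry and the deleted part of Ikzf4 are not stated. Gene positions came from GENCODE vM21 on GRCm38, matched by gene ID. The deposited barcode and gene lists were used only to name cells and genes.

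Cells with at least 500 genes, at least 1000 UMIs and under 10% mitochondrial UMIs were kept, which left 14191, 16131, 17530 and 17727 cells in WT 1, cKO 1, WT 2 and cKO 2. Doublets were scored with an own implementation of Scrublet's score (expected share 8%, simulated ratio 2). Its automatic threshold marked 4.39% of WT 1, and 0.0186, 0 and 0.0169% of cKO 1, WT 2 and cKO 2, where the top 5% of scores were removed in its place. This removed 623, 780, 859 and 880 cells. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 20 neighbours gave a shared-neighbour graph for Leiden clustering at resolution 1. T cell receptor and immunoglobulin variable, diversity and joining segments, mitochondrial, ribosomal, haemoglobin and sex-linked genes and Ikzf4 were left out of the variable genes.

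Clusters were named from markers fixed before the data were examined, as were the gene lists, the rule for named genes, the tests and the first set of alternatives. The naming thresholds were set after the clusters were seen. A Treg-like cluster had at least 50 CPM of Foxp3 and at least 8 of 12 Treg markers at 20 CPM or more. A recirculating-Treg-like cluster had a marker score over 0.8, more than 1 above its developing score, and among its top 10 genes at least as many recirculating or Treg markers as markers of any other class. A developing-Treg-like cluster had a recirculating score under 0 and a higher developing score. Its top 10 genes held at least as many developing or Treg markers as markers of any other class, immature SP aside. A cluster of 6702 cells met this with 0 such markers, and Pde3b and Rflnb were among its leading genes, as in the mature CD4 SP-like cluster. Cycling and interferon-responding clusters had at least 3 of their markers among their top 10 genes. Low-UMI clusters had a median UMI count under 60% of the median. These thresholds kept a cluster with recirculating score 1.54, led by Egr3, Il1r2 and Nr4a genes, out of the recirculating class (2.13, 1.31, 2.51 and 1.64% of WT 1, cKO 1, WT 2 and cKO 2). The low-UMI Treg-like cells were 13.3, 12.2, 15.5 and 12.2% and other Treg-like cells 17.2, 16.3, 18.9 and 16.9%.

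Raw counts were summed per library and class, and the sums tested ranged from 144120546 to 173336216 UMIs in Treg-like, 16367254 to 40660575 in recirculating-Treg-like, 55653864 to 76579291 in developing-Treg-like and 147284020 to 183384287 in all cells. Genes were tested with the quasi-likelihood test of edgeR 4.0.16 (robust, TMM, filterByExpr with a minimum count of 10, two-sided, Benjamini-Hochberg threshold 0.05), and DESeq2 1.42.0 was an alternative. DESeq2 gave no adjusted p for 1623, 0, 1401 and 1007 genes in these 4 comparisons, and these stayed without one. Printed CPM used TMM library sizes unless said otherwise. The difference between recirculating-Treg-like and developing-Treg-like cells was tested as an interaction term with library as a fixed effect. Shares of cells were tested in edgeR with the cells per library as offset. Adjusted p-values in the text come from edgeR, or for lists from camera in limma 3.58.1.

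The 28 gene lists were tested with camera on voom weights with a preset correlation of 0.01, and beside it camera with an estimated correlation and fry, for a shared direction and, after the data were seen, for either direction. Named genes were Ikzf4 and the Ikaros family, up to 10 higher and 10 lower genes with the largest change among those past the threshold, with at least 10 CPM in one genotype and the same sign in both batches, and up to 4 members of each list with the smallest p. The interaction named 5 genes each way by that rule. Receptor and immunoglobulin segments and genes with Gm or Rik names were outside the rule, so Igkc and Trav genes are named only as list members or after their values were seen. The examples printed were picked from these after their values were seen.

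The number after F in the titles was used as the replicate number, so WT 1 was paired with cKO 1 and WT 2 with cKO 2. The deviations of same-numbered libraries from their group means correlated across genes at 0.685 in Treg-like, 0.288 in recirculating-Treg-like, 0.544 in developing-Treg-like and 0.544 in all cells. Genes are not independent replicates, so this describes these libraries only. The fit without the block was the reported one and batch as a replicate block an alternative. The block leaves few residual degrees of freedom per gene. Its p-values therefore rest largely on the spread pooled across genes, and a very small one is not strong replication.

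The alternatives set before the data were examined were the replicate block, DESeq2 size factors, the DESeq2 test, no filter on low counts, each library left out, a stricter cell filter (1000 genes, 2000 UMIs, 5% mitochondrial), doublets kept, cells with a Foxp3 UMI, Leiden resolutions 0.5 and 2, clustering without the called genes, variable genes centred within batch, camera with an estimated correlation, and fry. Chosen after seeing the data were the fits without the low-UMI clusters, with equal cells per cluster (with and without the block), with Treg-like cells only or as the denominator, and the lists and interaction with each library left out.

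The tests were checked on counts simulated from the real means and library sizes. Of genes changed 1.25-fold edgeR recovered 42, 56, 58 and 24% in Treg-like, recirculating-Treg-like, developing-Treg-like and all cells, of those changed 1.5-fold 90, 86, 90 and 84%, and of those changed 2-fold 100% in each. It made 12, 9, 6 and 3 false calls. The interaction test recovered 20, 72, 92 and 98% of genes at 1.25, 1.5, 2 and 3-fold, with 6 false calls. In these simulations every gene of a comparison had the same dispersion, and no batch effect was set. Recovery of genes with a larger spread between libraries was therefore not checked. Camera called 5 of 5 lists raised 1.3-fold and 0 of 20 unchanged lists, and with an estimated correlation it called 5 of the 5. The simulated genes varied independently, so this check does not cover lists whose members vary together. In Treg-like cells the estimated correlation was 0.381 for recirculating and effector Treg genes, 0.916 for S phase genes and -0.0534 for NF-kB and TNF receptor genes. For class shares that changed 2-fold, edgeR called 97, 82, 37 and 14% at a coefficient of variation between libraries of 10, 14.1, 20 and 31.6%, with 0.09, 0.07, 0.05 and 0.02 false calls per simulation. Every simulated class had the same spread. Observed classes ran from 0.181% (low-UMI Treg-like, cKO) to 104% (innate-like T-like, WT), so these rates do not give their power or false calls. The observed coefficient was 13.8% in WT and 12.7% in cKO for the recirculating-Treg-like share, and in cKO 57.8% and 64.9% for the immature and mature CD4 SP-like shares. Libraries of a group differed beyond counting noise, with a chi-square per degree of freedom of 14.2 in WT and 26.8 in cKO.

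Other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2, scikit-image 0.26.0 and matplotlib 3.10.9. Raw reads were not analysed here.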

Results

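The series held single-cell RNA counts from 10x Genomics libraries of T cells sorted from mouse thymus. The 4 libraries fell into 2 genotypes with 2 libraries each, wild type (WT) and Ikzf4 conditional knockout (cKO). Ikzf4 encodes Eos, a zinc finger transcription factor of the Ikaros family that is expressed in Foxp3-positive regulatory T cells (Tregs). WT 1 and cKO 1 carry F1 in their titles and WT 2 and cKO 2 carry F2, taken here as batches F1 and F2. The title of the series names the homeostasis of Tregs and the Tregs that recirculate to the thymus, so the comparisons ask how the cell classes and their transcripts differ between the genotypes. The deposited files held 14798 barcodes with 160214864 unique molecular identifiers (UMIs) in WT 1, 16705 with 186301059 in cKO 1, 18190 with 193555390 in WT 2 and 18359 with 201456576 in cKO 2. The cells kept numbered 13568, 15351, 16671 and 16847 in the same order, with median depths of 9739, 10094, 9365 and 9752 UMIs. All changes are given as log2 fold change of cKO against WT with its standard error (SE), n = 2 libraries per genotype. Nothing in the labels says that the libraries came from separate animals, so the p-values measure only the spread between these libraries.

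Ikzf4 (ENSMUSG00000002578, chromosome 10, 128630843 to 128645991 on GRCm38) had a lower level in both cKO libraries than in either WT library, in recirculating-Treg-like, developing-Treg-like, all Treg-like and all cells. In recirculating-Treg-like cells it stood at 85.8 and 142 CPM (counts scaled to a fixed library total) in WT 1 and WT 2 and at 36.8 and 38.5 CPM in cKO 1 and cKO 2 (log2 -1.61, SE 0.37, adjusted p = 0.80). In developing-Treg-like cells it stood at 75.3 and 119 CPM in WT and 54.6 and 62.5 CPM in cKO (log2 -0.74, SE 0.33, adjusted p = 0.993). In all Treg-like cells the mean was 99.4 ± 33.7 CPM in WT and 51.8 ± 2.25 CPM in cKO (SD, log2 -0.94, SE 0.25, adjusted p = 0.412), and in all cells the log2 change was -1.11 (SE 0.24, adjusted p = 0.104). The WT libraries differed from each other, and the difference passed the test without WT 1 in Treg-like cells (log2 -1.26, adjusted p = 0.0151), recirculating-Treg-like cells (log2 -1.92, adjusted p = 2.91e-05), developing-Treg-like cells (log2 -1.03, adjusted p = 0.0146) and all cells (log2 -1.42, adjusted p = 0.000792). Without WT 2 it passed in recirculating-Treg-like cells (log2 -1.19, adjusted p = 0.00271) and in all cells (log2 -0.70, adjusted p = 0.0209), and DESeq2 gave adjusted p = 0.00499 and 0.0266 in those same classes with all 4 libraries. The labels do not say which part of the gene was deleted, and UMIs from outside that part would remain in deleted cells, so these levels do not measure how many cells had lost the gene. Of the other family members in Treg-like cells, Ikzf1 had a log2 change of 0.13 (SE 0.03, adjusted p = 0.353, and 0.0106 with batch as a block) and Ikzf3 of 0.11 (SE 0.09, adjusted p = 0.817, and 0.0199 with batch as a block). Ikzf2, which encodes Helios, was at -0.03 (SE 0.06, adjusted p = 0.926) and Ikzf5 at 0.08 (SE 0.05, adjusted p = 0.688). Adjusted over the list alone, 1 of the 5 Ikaros family members was higher and 1 lower in Treg-like cells.

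Recirculating-Treg-like cells, named from Treg markers and a score over recirculating markers such as Ccr6 and Nt5e, made up a smaller share of the cKO libraries. They were 18.0% of kept cells in WT 1 and 21.9% in WT 2, against 9.30% in cKO 1 and 11.1% in cKO 2, a 1.95-fold lower share (log2 -0.97, SE 0.23, adjusted p = 0.0303). In the clustering without called genes the log2 change of the share of recirculating-Treg-like cells was -0.93 (adjusted p = 0.0424). Both of their clusters were lower, the one led by S100a4, S100a6 and Ly6a (8.11% and 9.96% in WT, 4.05% and 4.27% in cKO) and the one with Ccl5 and Penk among its leading genes (9.88% and 11.9% in WT, 5.24% and 6.86% in cKO). The second, with 5293 cells against 4103, had Ccr6 at 229 CPM against 156 in the first, but S100a4 at 39.7 against 852, Il1rl1 at 4.85 against 170 and Klrg1 at 0.711 against 117 CPM. Its 10 leading genes held 1 recirculating marker, as many as CD8 or B cell markers. Conventional thymocyte classes with little Foxp3 were more frequent in cKO. Immature single-positive (SP)-like cells, marked by Ccr9 and Itm2a, were 0.273% (95% Clopper-Pearson interval 0.192 to 0.376) and 0.300% (0.223 to 0.395) of WT 1 and WT 2, against 3.48% (3.19 to 3.78) and 8.29% (7.88 to 8.72) of cKO 1 and cKO 2 (log2 4.36, SE 0.57, adjusted p = 0.0123). Mature CD4 SP-like cells, marked by Igfbp4, were 0.442% and 0.510% of the WT libraries and 3.50% and 9.44% of the cKO libraries (log2 3.76, SE 0.62, adjusted p = 0.0183). The intervals cover counting error only.

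Smaller classes moved as well. Innate-like T-like cells, with Zbtb16 and Klrb1c among their leading genes, were 1 and 8 cells in WT 1 and WT 2 and 36 and 100 cells in cKO 1 and cKO 2 (log2 3.79, SE 0.90, adjusted p = 0.0307). An unnamed cluster led by Igfbp4, Nrgn and Uhrf1 held 1 and 2 WT cells and 71 and 185 cKO cells (log2 6.19, SE 0.78, adjusted p = 0.0123). Myeloid or dendritic-like cells, led by Apoe and C1qb, fell from 0.553% and 0.534% in WT to 0.235% and 0.267% in cKO (log2 -1.11, SE 0.22, adjusted p = 0.0183). Developing-Treg-like cells were 44.4% and 36.4% of WT and 48.2% and 34.1% of cKO (log2 0.03, SE 0.27, adjusted p = 0.929). Cycling Treg-like cells were 0.811% and 0.906% of WT and 1.09% and 1.5% of cKO (log2 0.60, SE 0.26, adjusted p = 0.133, and 0.0354 with batch as a block). Without cKO 1 the cycling share passed the test (log2 0.80, adjusted p = 0.00906), and without cKO 2 the share of cycling Treg-like cells was at log2 0.35 (adjusted p = 0.290). The other classes had adjusted p from 0.153 to 0.728.

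Cells that were not Treg-like made up 1.46% of WT 1, 1.63% of WT 2, 8.16% of cKO 1 and 20.1% of cKO 2. The cells were sorted, and the gate is not stated, so the sort can set this share and, through it, every share of kept cells. Among Treg-like cells alone the recirculating share was 18.3% and 22.3% in WT and 10.1% and 13.9% in cKO (log2 -0.75, SE 0.23, adjusted p = 0.187, and 0.000697 with batch as a block). On the same basis developing-Treg-like cells were 45.1% and 37.0% of WT and 52.5% and 42.7% of cKO (log2 0.21, SE 0.17, adjusted p = 0.462, and 0.00793 with the block). Cycling Treg-like cells were 0.823% and 0.921% of WT and 1.19% and 1.88% of cKO (log2 0.81, SE 0.29, adjusted p = 0.187, and 0.00793 with the block). With 2 libraries per genotype an exact permutation test cannot go below p = 0.33. The 6 shares of kept cells that passed lost the call without WT 1 and without WT 2, where the recirculating share was at log2 -1.10 (adjusted p = 0.202) and -0.82 (adjusted p = 0.187). Without single libraries the log2 change ran from 2.95 (without cKO 2) to 5.67 (without WT 2) for the innate-like T-like share, from 3.59 (without cKO 2) to 4.85 (without cKO 1) for the immature SP-like share and from 2.87 (without cKO 2) to 4.30 (without cKO 1) for the mature CD4 SP-like share. The myeloid or dendritic-like share also lost it with the stricter cell filter (adjusted p = 0.0764), and the innate-like T-like share at Leiden resolution 0.5 (adjusted p = 0.0505). In Treg-like cells 79.2, 78.2, 77.7 and 73.6% of cells had a Foxp3 UMI in WT 1, WT 2, cKO 1 and cKO 2, at median depths of 9747, 9362.5, 9961 and 9507 UMIs. In the cells that were not Treg-like the values were 8.59, 12.2, 2.79 and 2.01%, at 9164.5, 9507, 11569 and 10512 UMIs.

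**Figure D1:**
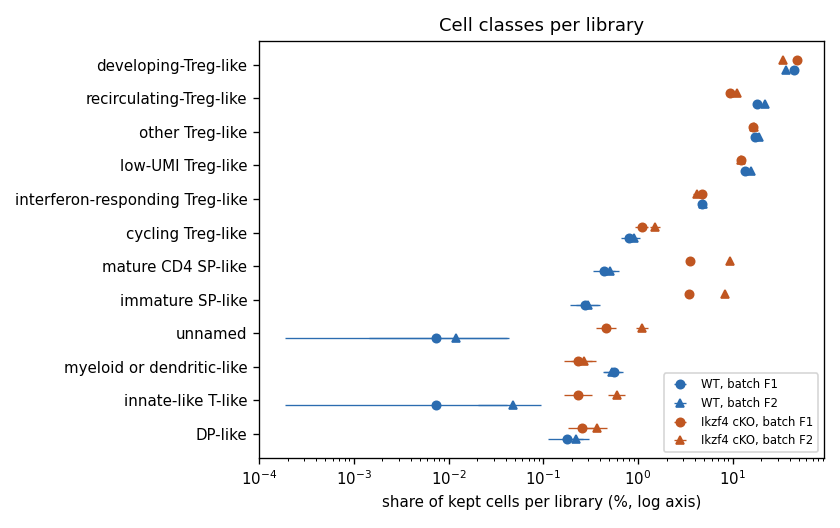
Share of kept cells in each class, per library, in percent on a log axis. WT libraries are blue and cKO libraries orange, circles are batch F1 and triangles batch F2, and bars are 95% Clopper-Pearson intervals. Recirculating-Treg-like cells were at 18.0% and 21.9% in WT and 9.30% and 11.1% in cKO.

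In the pool of all Treg-like cells, transcripts of the calcium-binding proteins S100a4 and S100a6 fell, and 2 genes beside Foxp3 on the X chromosome rose. S100a4 (ENSMUSG00000001020, chromosome 3, 90603771 to 90606045) went from 95.5 ± 2.16 to 45.0 ± 1.5 CPM (SD, log2 -1.09, SE 0.04, adjusted p = 0.00592). S100a6 (ENSMUSG00000001025, chromosome 3, 90612882 to 90624181) went from 93.3 ± 5.53 to 43.1 ± 2.14 CPM (log2 -1.11, SE 0.06, adjusted p = 0.0143). Ccdc22, an endosomal sorting gene, rose from 12.8 ± 0.112 to 22.5 ± 0.400 CPM (log2 0.82, SE 0.04, adjusted p = 0.0143). Syp, which encodes synaptophysin, a protein of synaptic vesicles, rose from 3.29 to 10.1 CPM (log2 1.61, SE 0.08, adjusted p = 0.0143). These 4 were the genes edgeR called among 16736 tested, beside 1634 at unadjusted p under 0.05. With batch as a block 1470 genes passed, 564 higher and 906 lower, and DESeq2 called 300, the 4 among them in both fits. The count was 5 without WT 1, 130 without cKO 1, 2 without WT 2 and 8 without cKO 2. Syp in Treg-like cells and Ccdc22 in Treg-like cells lost their calls without WT 1 (adjusted p = 0.0695 and 0.0839) and without WT 2 (adjusted p = 0.175 for both). S100a4 and S100a6 also mark recirculating-Treg-like cells. With equal cells per cluster in every library their log2 changes were -0.29 (SE 0.17, adjusted p = 0.999) and -0.41 (SE 0.08, adjusted p = 0.686). With equal cells and the block S100a6 in Treg-like cells passed (log2 -0.41, adjusted p = 2.34e-17) and S100a4 in Treg-like cells did not (log2 -0.28, adjusted p = 0.0873).

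Genes of recirculating and effector Tregs were lower as a group in the Treg-like pool. Of the 36 measured members 34 had lower values, 2 fell over all genes tested, 26 with batch as a block, and 25 adjusted over the list alone (median log2 -0.51, camera adjusted p = 4.98e-29). With an estimated correlation the adjusted p was 0.375. Examples that did not pass were the redox gene Glrx (34.0 to 24.0 CPM, log2 -0.50, SE 0.04, adjusted p = 0.0702, and 1.56e-05 with the block) and the costimulatory receptor gene Icos (166 to 118 CPM, log2 -0.49, SE 0.06, adjusted p = 0.108, and 6.85e-06 with the block). Suppressive effector molecules were lower too, with 16 of 19 members lower, 14 of them passing adjusted over the list alone or with the block (median log2 -0.41, camera adjusted p = 6.11e-11). Camera with an estimated correlation put the adjusted p at 0.375. Among them Fgl2, which encodes a secreted suppressive protein, was at 18.9 ± 3.57 CPM in WT and 8.95 ± 0.281 CPM in cKO (SD, log2 -1.08, SE 0.14, adjusted p = 0.158, 0.00418 with the block and 0.0413 without WT 1). Glrx passed without cKO 1 (adjusted p = 0.019). With equal cells per cluster the log2 changes were -0.07 for Glrx in Treg-like cells, -0.09 for Icos in Treg-like cells and -0.25 for Fgl2 in Treg-like cells. The recirculating-Treg-like share of the same cells was lower in cKO, at 10.1% and 13.9% against 18.3% and 22.3%.

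Other lists lower in Treg-like cells were the Treg core (14 of 20 members lower, 5 passing over the list alone, 9 lower and 3 higher with the block, median log2 -0.06, camera adjusted p = 0.00249), T cell receptor (TCR) signal response (19 of 24, median -0.11, adjusted p = 7.41e-05), NF-kB and TNF receptor genes (16 of 19, median -0.05, adjusted p = 0.000199), egress and homing receptors (15 of 27, median -0.06, adjusted p = 0.00261), glycolysis (14 of 15, median -0.07, adjusted p = 0.00249), follicular helper genes (6 of 7, median -0.17, adjusted p = 0.000326) and B cell markers (7 of 9, median -0.59, adjusted p = 0.000326). With an estimated correlation the adjusted p of these lists was 0.461, 0.375, 0.375, 0.375, 0.390, 0.375 and 0.461 in the same order. Foxp3 itself was at 322 ± 2.98 CPM in WT and 266 ± 13.3 CPM in cKO (SD, log2 -0.28, SE 0.04, adjusted p = 0.187, 0.0012 with the block, 0.0358 without cKO 1 and 0.033 with equal cells per cluster). The B cell marker Igkc was at 3.84 and 0.861 CPM (log2 -2.16, SE 0.25, adjusted p = 0.107, and 7.57e-06 with the block).

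Lists higher in Treg-like cells were led by cell cycle genes. All 25 G2 and M phase genes were higher (median log2 0.74, camera adjusted p = 3.74e-14, and 0.461 as the adjusted p with an estimated correlation), for example Nusap1 of the mitotic spindle at 9.52 ± 0.139 CPM in WT and 18.0 ± 5.78 CPM in cKO (SD, log2 0.91, SE 0.23, adjusted p = 0.379, and 0.00375 without cKO 1). Without cKO 2 Nusap1 in Treg-like cells was at log2 0.54 (adjusted p = 0.0787). All 24 S phase genes were higher (median 0.16, adjusted p = 4.05e-06, and 0.505 as the adjusted p with an estimated correlation), for example Pcna, the replication clamp (124 to 143 CPM, log2 0.21, SE 0.05, adjusted p = 0.284, and 0.00242 with the block). None of the G2 and M phase genes and 7 of the S phase genes passed with batch as a block. With equal cells per cluster the medians were 0.11 (22 of 25 higher) and -0.02 (8 of 24 higher), Nusap1 in Treg-like cells was at 0.19 and Pcna in Treg-like cells at 0.06. Cycling Treg-like cells were 1.19% and 1.88% of Treg-like cells in cKO against 0.823% and 0.921% in WT. Foxp3-repressed and conventional T cell genes were higher in 16 of 20 members (median 0.15, adjusted p = 0.000553, and 0.375 as the adjusted p with an estimated correlation), although Il7r, the interleukin 7 receptor gene in that list, was at 146 CPM in WT and 116 CPM in cKO (log2 -0.34, SE 0.06, adjusted p = 0.197, and 4.13e-05 with the block). With equal cells per cluster Il7r in Treg-like cells was at log2 -0.03 (adjusted p = 0.999). Mature CD4 SP and naive T cell genes (15 of 16, median 0.11, adjusted p = 0.000326), developing Treg and immature SP genes (16 of 22, median 0.06, adjusted p = 0.0379), interferon response (26 of 32, median 0.04, adjusted p = 0.00479), oxidative phosphorylation (33 of 33, median 0.06, adjusted p = 4.05e-06) and mitochondrially encoded genes (13 of 13, median 0.06, adjusted p = 0.00308) were also higher. With an estimated correlation these last 5 lists had adjusted p = 0.461, 0.667, 0.505, 0.505 and 0.505. The share of cells outside the Treg-like classes was higher in the same cKO libraries, at 8.16% and 20.1% against 1.46% and 1.63%.

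The other 11 lists did not pass in Treg-like cells. These were the Ikaros family (adjusted p = 0.521), effector cytokines (0.683), IL-2 and STAT5 response (0.0688), apoptosis and survival (0.330), dissociation stress (0.521), MHC genes (0.151), CD8 lineage (0.175, and 0.00671 lower with batch as a block), double-positive (DP) thymocyte genes (0.238), innate-like T cell genes (0.683), myeloid and dendritic genes (0.414) and stroma and erythroid genes (0.235). The median, the mean and the direction of the test differed in sign for the Ikaros family (median 0.08, mean -0.13), IL-2 and STAT5 response (median 0.03, mean -0.03) and DP thymocyte genes (median 0.02, mean -0.01). Camera with an estimated correlation called 0 lists in each of the 3 classes, and so did fry, limma's rotation test, for a shared direction. Fry with batch as a block called 1 list in Treg-like cells (TCR signal response, adjusted p = 0.00114) and 1 in recirculating-Treg-like cells (myeloid and dendritic genes, adjusted p = 0.00205). Tested by fry for changes in either direction, 15 lists passed in Treg-like cells, 0 in recirculating-Treg-like cells and 1, the Treg core, in developing-Treg-like cells (adjusted p = 0.0281). In Treg-like cells it was 0.0149 for TCR signal response and 0.0257 for recirculating and effector Treg genes.

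In recirculating-Treg-like cells the genes that rose included Gbp2b, Tnfsf8 and St8sia1, and those that fell included Cep112, Cd74 and Igkc. Gbp2b (ENSMUSG00000040264, chromosome 3, 142594847 to 142619179), an interferon-inducible GTPase with close paralogs that could share its reads, rose from 4.33 ± 0.307 to 11.9 ± 0.908 CPM (SD, log2 1.47, SE 0.13, adjusted p = 0.00562). Tnfsf8 (ENSMUSG00000028362, chromosome 4, 63831308 to 63861347), which encodes CD30 ligand, rose from 169 ± 7.45 to 238 ± 10.3 CPM (log2 0.49, SE 0.05, adjusted p = 0.0122). St8sia1 (ENSMUSG00000030283, chromosome 6, 142821545 to 142964452), a ganglioside sialyltransferase gene, rose from 49.2 ± 1.36 to 68.2 ± 4.51 CPM (log2 0.48, SE 0.06, adjusted p = 0.0237). Cep112 (ENSMUSG00000020728, chromosome 11, 108425192 to 108860615), a centrosomal protein gene, fell from 25.1 ± 0.917 to 13.6 ± 0.234 CPM (log2 -0.89, SE 0.08, adjusted p = 0.00514). Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), the MHC class II invariant chain gene, fell from 131 to 95 ± 4.13 CPM (log2 -0.46, SE 0.05, adjusted p = 0.0122). Igkc, an immunoglobulin light chain gene, fell from 15.3 ± 1.10 to 5.43 ± 0.310 CPM (log2 -1.50, SE 0.12, adjusted p = 0.00514). Both are abundant in antigen-presenting or B cells, the myeloid or dendritic-like share was lower in the same cKO libraries (0.553% and 0.534% in WT, 0.235% and 0.267% in cKO), and free RNA from such cells was not estimated. The B cell genes were lower in this class in 5 of 7 members (camera adjusted p = 0.00579, and 0.656 with an estimated correlation), while the myeloid and dendritic genes were higher in 9 of 13 (adjusted p = 0.592). Syp (log2 1.21, SE 0.12, adjusted p = 0.00922) and Plp2 (log2 0.34, SE 0.04, adjusted p = 0.0394) beside Foxp3 rose as well.

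Altogether 12 genes passed in recirculating-Treg-like cells, 8 higher and 4 lower of 13634 tested, beside 827 at unadjusted p under 0.05. The other 4, outside the rule for named genes and named after their values were seen, were Trav17, Ccl20 and 2610204G07Rik, which were higher, and Trav4-3, which was lower. With batch as a block 98 genes passed and DESeq2 called 33, the 12 among them in both. Without cKO 1 the count was 157, without cKO 2 it was 78, without WT 1 it was 8 and without WT 2 it was 2, none of them among the 12. Without WT 2 the adjusted p ranged from 0.0743 for Igkc to 0.359 for Plp2 among the genes named above. Without WT 1 Syp, Tnfsf8, St8sia1, Plp2 and Cd74 also lost their calls (adjusted p = 0.0777, 0.110, 0.174, 0.617 and 0.161). Plp2 had adjusted p = 0.0508 with equal cells per cluster and 0.0686 at Leiden resolution 2, and at Leiden resolution 0.5 Tnfsf8, St8sia1 and Cd74 had 0.664, 0.335 and 0.468. The log2 changes at that resolution were 0.89 for Tnfsf8 in recirculating-Treg-like cells, 0.78 for St8sia1 in recirculating-Treg-like cells and -0.49 for Cd74 in recirculating-Treg-like cells, so the calls were lost without smaller changes. Syp in recirculating-Treg-like cells was at 2.36 there (adjusted p = 0.00815).

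In the pool of recirculating-Treg-like cells the list of recirculating and effector Treg genes was also lower, in 29 of 36 members (median log2 -0.14, camera adjusted p = 1.42e-06), with 2 lower and 1 higher adjusted over the list alone, and 3 lower and 1 higher with batch as a block. Camera with an estimated correlation put the adjusted p at 0.814. The class pools 2 clusters with S100a4 at 852 and 39.7 CPM. Their mix was not held equal for this list, so it can contribute. The inhibitory receptor gene Tigit was at 239 ± 3.74 CPM in WT and 168 ± 21.4 CPM in cKO (SD, log2 -0.51, SE 0.08, adjusted p = 0.191), and passed without cKO 1 (5.74e-05), without cKO 2 (0.00157), with equal cells per cluster (0.006) and with DESeq2 (2.86e-05). Ly6a went the other way, at 316 and 368 CPM (log2 0.22, SE 0.05, adjusted p = 0.291, 0.0423 with the block and 0.0297 without cKO 2). Foxp3-repressed and conventional T cell genes were higher in 13 of 18 members (median 0.24, adjusted p = 0.000281), 3 of them passing adjusted over the list alone and 2 with batch as a block. With an estimated correlation the adjusted p was 0.655. Examples were Bach2, a transcription factor of resting T cells (221 to 259 CPM, log2 0.23, SE 0.05, adjusted p = 0.222, 0.0128 with the block and 0.0374 without cKO 2), and Cd40lg, the CD40 ligand gene (14.4 ± 0.940 to 24.2 ± 5.17 CPM, SD, log2 0.76, SE 0.15, adjusted p = 0.271). Cd40lg in recirculating-Treg-like cells passed without cKO 1 (0.000217), without cKO 2 (0.0407), with DESeq2 (0.00804) and in the clustering without called genes (0.0235).

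Effector cytokines (6 of 11 higher, Tnfsf8 rose, 2 passed over the list alone, median log2 0.09, camera adjusted p = 0.0147), mitochondrially encoded genes (13 of 13 higher, median 0.09, adjusted p = 0.000138), interferon response (22 of 32 higher, median 0.02, adjusted p = 0.0459) and innate-like and gamma delta T cell genes (7 of 9 higher, 1 passing over the list alone, median 0.36, adjusted p = 0.011) were higher in recirculating-Treg-like cells. Camera with an estimated correlation put the adjusted p at 0.655, 0.814, 0.860 and 0.655. The gamma delta receptor gene Trdc was at 0.750 CPM in WT and 2.47 CPM in cKO (log2 1.68, SE 0.28, adjusted p = 0.139, 0.0222 with the block and 0.0362 without cKO 1). TCR signal response (16 of 24 lower, median -0.11, adjusted p = 0.0281), NF-kB and TNF receptor genes (15 of 19, median -0.05, adjusted p = 0.0429), glycolysis (13 of 15, median -0.07, adjusted p = 0.011) and B cell markers (5 of 7, Igkc fell, median -0.16, adjusted p = 0.00579) were lower. With an estimated correlation the adjusted p was 0.814, 0.814, 0.814 and 0.655. The other 18 lists had adjusted p from 0.0728 to 0.950, and among them the median, the mean and the direction of the test differed in sign for the Ikaros family, developing Treg, S phase, CD8 lineage, DP thymocyte, IL-2 and STAT5, and stroma and erythroid genes. Without WT 1 the number of lists called was 6, against 10 with all libraries. Innate-like T-like cells as a class were more frequent in the same cKO libraries.

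In developing-Treg-like cells 3 genes next to Foxp3 on the X chromosome rose and Foxp3 itself fell. Syp (ENSMUSG00000031144, chromosome X, 7638471 to 7653256) rose from 1.38 ± 0.425 to 10.1 ± 0.150 CPM (SD, log2 2.86, SE 0.16, adjusted p = 0.000855). Ccdc22 (ENSMUSG00000031143, 7593809 to 7605517) rose from 12.2 ± 0.0918 to 26.7 ± 1.60 CPM (log2 1.13, SE 0.06, adjusted p = 0.000732). Plp2 (ENSMUSG00000031146, 7667941 to 7671390), a membrane proteolipid gene, rose from 53.4 ± 0.342 to 109 ± 3.49 CPM (log2 1.02, SE 0.04, adjusted p = 4.82e-05). Foxp3 (ENSMUSG00000039521, 7573644 to 7595245), the lineage factor of Tregs, fell from 388 ± 15.4 to 303 ± 1.38 CPM (log2 -0.36, SE 0.04, adjusted p = 0.0328). The metalloprotease gene Adam19 (ENSMUSG00000011256, chromosome 11, 46055992 to 46147343) rose from 64.0 ± 0.228 to 86.7 ± 1.14 CPM (log2 0.44, SE 0.03, adjusted p = 0.00318). Foxp3 and Ccdc22 overlap at their ends on opposite strands, and UMIs in the overlap are uncertain if the counting did not use strand. Flicr (7573600 to 7581027) overlaps Foxp3 on the same strand, and was at log2 -0.0017 (SE 0.06). Prickle3, between Syp and Plp2 and overlapping Plp2 at its end, was at log2 0.45 (SE 0.06, adjusted p = 0.0893, and 7.97e-13 with batch as a block).

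These 5 genes were all that edgeR called of 14447 tested in developing-Treg-like cells, 4 higher and 1 lower, beside 660 at unadjusted p under 0.05. With batch as a block 543 genes passed, 353 higher and 190 lower, and DESeq2 called 18, the 5 among them in both. The count was 10 without WT 1, 11 without cKO 1, 14 without WT 2 and 18 without cKO 2, and Foxp3 lost its call without WT 2 (log2 -0.31, adjusted p = 0.0776). Of the 25 other genes tested that start within 500 kb of Foxp3, 3 passed and 15 were higher. The block raised the number that passed to 6, the added ones being Prickle3, Gm14703 (log2 1.93, SE 0.47, adjusted p = 0.870, blocked 0.0201) and Gata1, which was lower (log2 -0.16, SE 0.08, adjusted p = 0.993, blocked 0.00432). The median log2 change of the 399 other X-linked genes was 0.0009.

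**Figure D2:**
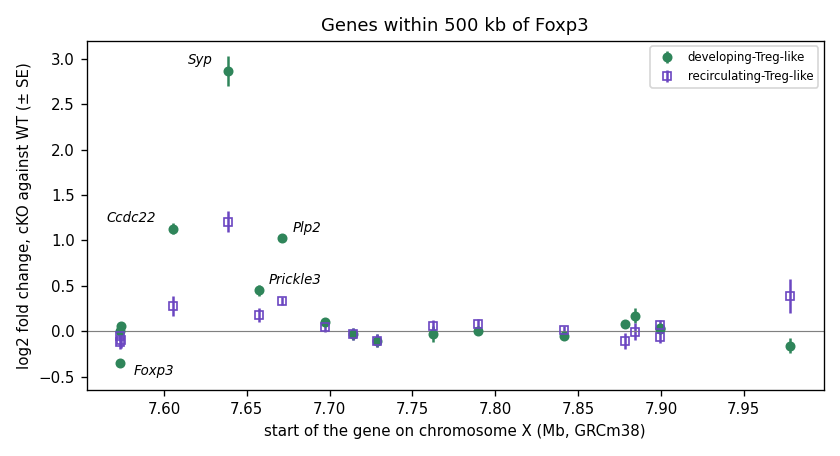
Log2 fold change (cKO against WT, bars are SE) of genes with at least 10 CPM in one genotype against the position of their start on chromosome X (Mb, GRCm38), in developing-Treg-like (filled circles) and recirculating-Treg-like cells (open squares). Syp, Ccdc22 and Plp2 stood at 2.86, 1.13 and 1.02 in developing-Treg-like cells, and Foxp3 at -0.36.

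Respiratory chain genes were slightly higher throughout developing-Treg-like cells. All 33 oxidative phosphorylation genes were higher (median log2 0.06, camera adjusted p = 2.39e-11), 11 of them passing with batch as a block, and all 13 mitochondrially encoded genes (median 0.10, adjusted p = 1.73e-10), 8 of them with the block. Camera with an estimated correlation put the adjusted p at 0.795 and 0.616. The complex I gene mt-Nd5 was at 693 ± 0.317 CPM in WT and 746 ± 1.41 CPM in cKO (SD, log2 0.11, SE 0.03, adjusted p = 0.993, and 0.000275 with the block). IL-2 and STAT5 response genes were higher in 13 of 19 members, 4 of them passing adjusted over the list alone and 6 higher and 1 lower with the block (median 0.06, adjusted p = 0.00105), and effector cytokines in 6 of 7, 2 over the list alone (median 0.06, adjusted p = 0.0134). With an estimated correlation the adjusted p was 0.616 for both. Examples were Cish, a feedback inhibitor of cytokine signalling (201 to 227 CPM, log2 0.18, SE 0.03, adjusted p = 0.551, and 4.93e-10 with the block), Bcl2, the survival gene (544 to 607 CPM, log2 0.16, SE 0.03, adjusted p = 0.562, and 5.85e-09 with the block), and Tnfsf8 (53.6 to 67.8 CPM, log2 0.34, SE 0.08, adjusted p = 0.919, and 1.66e-15 with the block). At Leiden resolution 0.5 Cish in developing-Treg-like cells was at 0.06 and Bcl2 in developing-Treg-like cells at 0.09 (adjusted p above 0.999 for both), and with equal cells per cluster they were at 0.08 and 0.10. The developing-Treg-like cluster led by Lta, Gpr83 and Il2ra was 7.59% and 6.70% of WT and 9.35% and 7.11% of cKO. Lists were not tested with equal cells per cluster here, so a changed mix of clusters can contribute. NF-kB and TNF receptor genes were lower in 16 of 19 members (median -0.04, adjusted p = 0.0134, and 0.616 with an estimated correlation).

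The other 23 lists did not pass in developing-Treg-like cells, with adjusted p from 0.0795 to 0.969. Recirculating and effector Treg genes had a median log2 change of -0.00 over 31 members (adjusted p = 0.629), with Crip1 at 289 and 334 CPM (log2 0.21, SE 0.03, adjusted p = 0.173, and 3.85e-14 with the block). At Leiden resolution 0.5 Crip1 in developing-Treg-like cells was at 0.07. With batch as a block 11 lists passed, the added ones being the Treg core (0.0135, higher), suppressive effector molecules (0.0141, higher), egress and homing receptors (0.0141, higher), developing Treg and immature SP genes (0.03, lower), interferon response (0.0043, lower) and dissociation stress (0.0112, lower). The number of lists called was 10 without WT 1, 8 without WT 2 and 8 without cKO 2. The median, the mean and the direction of the test differed in sign for recirculating and effector Treg, Foxp3-repressed, apoptosis and survival, glycolysis, mature CD4 SP, follicular helper, and stroma and erythroid genes.

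The effect of the genotype differed between the 2 Treg stages for 81 genes, by the interaction term of edgeR over 15321 genes, beside 1178 at unadjusted p under 0.05. The change was higher in recirculating-Treg-like cells for 38 genes and lower for 43. The interaction was not fitted with equal cells per cluster. A changed mix of clusters within a class can therefore contribute to these differences. On the log2 scale Plp2 and Syp rose more in developing-Treg-like cells than in recirculating-Treg-like cells (difference of log2 changes -0.70, SE 0.05, adjusted p = 7.42e-08, and -1.69, SE 0.19, adjusted p = 9.68e-05), and Ccdc22 likewise (-0.86, SE 0.12, adjusted p = 0.00251). Syp went from 1.38 to 10.1 CPM in developing-Treg-like and from 5.29 to 12.2 CPM in recirculating-Treg-like cells. Its larger log2 change thus goes with a low WT level. Ikzf4 was lower by more in recirculating-Treg-like cells (-0.87, SE 0.06, adjusted p = 7.42e-08). Foxp3 was at log2 -0.36 in developing-Treg-like cells and -0.06 in recirculating-Treg-like cells (243 and 233 CPM), a difference of 0.29 (SE 0.05, adjusted p = 0.0044). With batch as a block 366 genes passed, 81 of them the same genes. The count was 234 without cKO 1, 156 without WT 2 and 159 without cKO 2.

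**Figure D3:**
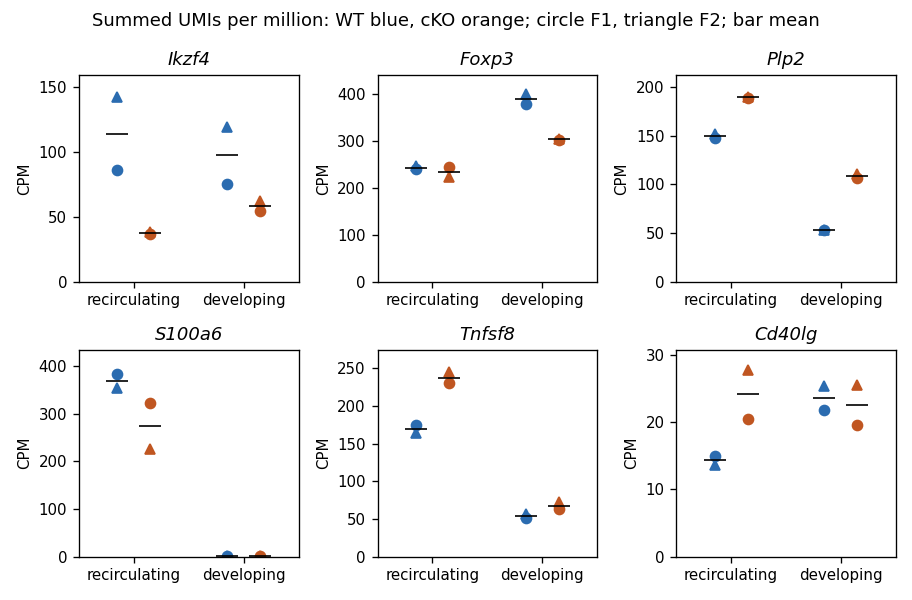
CPM of Ikzf4, Foxp3, Plp2, S100a6, Tnfsf8 and Cd40lg in recirculating-Treg-like and developing-Treg-like cells. Points are libraries (WT blue, cKO orange, circles batch F1, triangles batch F2), black lines are means of 2 libraries, and each axis starts at 0. Plp2 stood at 150 CPM in WT and 189 CPM in cKO recirculating-Treg-like cells, and at 53.4 and 109 CPM in developing-Treg-like cells.

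Summed over all cells, without regard to class, Chl1 and histone genes rose, and complement genes, Apoe and genes that led a recirculating-Treg-like cluster fell. Chl1 (ENSMUSG00000030077, chromosome 6, 103510586 to 103750211), a cell adhesion gene that led the immature SP-like cluster, rose from 2.19 ± 0.209 to 19.6 ± 9.01 CPM (SD, log2 3.17, SE 0.37, adjusted p = 0.0437, and 0.135 with batch as a block). The complement genes C1qa, C1qb and C1qc and the lipid transport gene Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188) fell (log2 -2.38, -2.38, -2.51 and -2.05, SE 0.25, 0.18, 0.24 and 0.13, adjusted p = 0.0332, 0.02, 0.0271 and 0.02). Tigit (log2 -1.42, SE 0.13, adjusted p = 0.0294), Fgl2 (log2 -1.16, SE 0.13, adjusted p = 0.0332) and Il1rl1, the interleukin 33 receptor gene (log2 -1.30, SE 0.18, adjusted p = 0.0491, and 0.15 with the block), fell. S100a4 (log2 -1.27, SE 0.05, adjusted p = 0.00449) and S100a6 (log2 -1.20, SE 0.05, adjusted p = 0.00449) fell, as did Bicd1, a dynein adaptor gene (log2 -1.24, SE 0.15, adjusted p = 0.0363). Sema4a, Dtx1, Tspan9, Marcks, Tmem108 and Ccdc22 rose (log2 0.78, 0.64, 0.53, 0.52, 0.47 and 0.81, SE 0.10, 0.09, 0.07, 0.08, 0.05 and 0.05, adjusted p = 0.0405, 0.0398, 0.0405, 0.0485, 0.0271 and 0.0139). The histone genes Hist1h2ab, Hist1h2ae and Hist1h3f rose too (log2 0.94, 0.77 and 0.53, SE 0.13, 0.10 and 0.06, adjusted p = 0.0491, 0.0437 and 0.0293), as members of a family of near-identical copies whose counts are uncertain.

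In all cells edgeR called 300 genes, 62 higher and 238 lower of 17306 tested, beside 3112 at unadjusted p under 0.05. With batch as a block 2075 passed (757 higher and 1318 lower), 297 of the 300 among them. DESeq2 called 1141, 438 higher and 703 lower. Cells that were not Treg-like made up 8.16% and 20.1% of the cKO libraries against 1.46% and 1.63% of WT, and in Treg-like cells only the count was 4. In Treg-like cells only, the log2 changes of C1qb, C1qc and Apoe were 0.09, 0.12 and -0.06 (adjusted p = 0.970, 0.933 and 0.936). Those of Chl1, Sema4a, Dtx1, Tspan9, Marcks and Tmem108 were 0.75, 0.34, 0.41, 0.28, 0.16 and 0.32 there, with adjusted p from 0.162 for Dtx1 to 0.609 for Marcks. The histone genes, Tigit, Fgl2, Il1rl1, Bicd1 and C1qa did not pass there either, while Ccdc22, S100a4 and S100a6 did (0.82, -1.09 and -1.11). The count was 1251 without cKO 1 and 36 without WT 2. Without WT 2 Chl1 had adjusted p = 0.513, and the higher genes other than Ccdc22 lost their calls (0.0654 for Tmem108 to 0.188 for Sema4a), as did C1qa (0.0654), Il1rl1 (0.204) and Bicd1 (0.0538). Without WT 1 Chl1 had 0.367, and Sema4a, Dtx1, Tspan9, Marcks, the histone genes and Il1rl1 had 0.0591 for Dtx1 to 0.0932 for Hist1h2ae in all cells. Without cKO 2 C1qb (0.0534), C1qc (0.0928), C1qa (0.0655), Apoe (0.0988), Tigit (0.260), Fgl2 (0.172), Bicd1 (0.147), Il1rl1 in all cells (0.0995), Tspan9 (0.0592) and Hist1h2ab (0.135) lost their calls. Without cKO 1 Tigit (0.181), Fgl2 (0.106) and Bicd1 (0.0679) lost theirs. Ccdc22, S100a4 and S100a6 passed without any 1 of the 4 libraries.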

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

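Of the tests in this part, the count of called genes beside Foxp3, the comparison of the Foxp3 change between the classes, and both tests of the recirculating gene list and that of Cd40lg were chosen only after the result was seen. The test of the whole X chromosome and 1 of the 2 tests of SP-like genes were written before theirs.

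The effect of the genotype differed between recirculating-Treg-like and developing-Treg-like cells for 81 genes by the interaction test of edgeR. The difference of log2 changes, recirculating minus developing, was 2.02 for Gbp2b (SE 0.43, adjusted p = 0.0344), which lost its call without WT 2 (1.77, adjusted p = 0.176) and without cKO 2 (1.98, adjusted p = 0.0502), while for the Gbp2b difference between the classes its alternatives ran from 0.00112 to 0.176. It was 1.48 for Tmem176a and 1.24 for Tmem176b (SE 0.24 and 0.18, adjusted p = 0.00406 and 0.00135). These 2 overlap each other on opposite strands, so their counts are uncertain if the counting did not use strand. In developing-Treg-like cells these 3 genes were at low levels. Gbp2b was at 0.241 and 0.161 CPM in WT and cKO there (log2 -0.58, SE 0.39, adjusted p = 0.993), with 9 to 16 UMIs for Gbp2b per library, so part of its difference rests on few counts. Tmem176a was at 1.38 and 1.0004 CPM and Tmem176b at 2.72 and 2.36 CPM. For Rflnb it was 0.78 (SE 0.12, adjusted p = 0.00311), and for Pde4a, a phosphodiesterase gene, it was -0.80 (SE 0.14, adjusted p = 0.00769). For Cd40lg it was 0.82 (SE 0.11, adjusted p = 0.000878), for Ikzf4 -0.87 and for Foxp3 0.29. For the neighbours of Foxp3 it was -1.69 for Syp, -0.86 for Ccdc22 and -0.70 for Plp2.

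The first pattern is the rise of genes beside Foxp3 in cKO developing-Treg-like cells. A shift of the whole X chromosome was argued against, since the median log2 change of the 399 other X-linked genes was 0.0009 (quartiles -0.0518 and 0.0585). A loss of Foxp3 reads alike in every class was argued against by the difference of 0.2881 (SE 0.05) between the classes. An altered Foxp3 allele in the cKO libraries was not tested by the 3 called genes within 500 kb of Foxp3, since these genes made the pattern. It stays open, as does an effect of the loss of Ikzf4: the labels name no such allele, and it would be confounded with the genotype.

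The second pattern is the lower level of recirculating and effector Treg genes in cKO Treg-like cells. The sums behind this pattern already left out the clusters that are not Treg-like, so dilution by cells of those clusters could not act on it. The test written for that dilution therefore decided nothing. In it, the log2 ratio of the recirculating share among Treg-like cells alone was -0.7531 (SE 0.23, edgeR adjusted p = 0.187). With equal cells per cluster the median of the list was -0.119, against -0.51 in the pool. Fewer recirculating-Treg-like cells in the pool may thus account for a part of it. The markers that named those cells are all members of the list, and clusters were formed from expression. Equal cells per cluster can therefore even out the list itself, and the fit cannot tell how much was due to cell numbers. With equal cells 25 of 36 members were still lower, so a change within the cells stays open, as does an effect of the sort.

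The third pattern is the higher Cd40lg of cKO recirculating-Treg-like cells, where transcripts of SP-like cells were the question. The 31 genes that mark the SP-like clusters were not higher as a set in these cells (16 and 17 of 31 in F1 and F2, median rise 0.151 and 0.207% of the SP-like level, smallest exact binomial p = 0.7201), which left no rise to explain. The tests written for free RNA and for misplaced SP-like cells compare other cells with that rise and were void: the medians were -1.0049 and -0.685% in developing-Treg-like cells (6 and 12 of 31 higher, exact binomial p = 0.0009 and 0.281), and 0.044 and 0.235% in recirculating-Treg-like cells with a Foxp3 UMI. Genes of the same libraries are not independent replicates, so these binomial p-values describe these libraries only. Cd40lg and Igfbp4 are themselves among the 31 genes. Cd40lg, at 15.2 and 20.7 CPM without TMM in WT and cKO of F1 and 13.8 and 27.1 in F2, would need 4.23 and 10.2% of SP-like RNA, and the median rise of the SP-like genes was at most 3.574% of that. This argues against RNA or cells of the pooled SP-like clusters. Igfbp4 went from 1.91 to 1.28 and from 1.21 to 2.82 CPM where rises of 20.8 and 50.1 would be needed. It was at 847 CPM in the mature SP-like cluster and 62.3 CPM in the immature one, so it speaks to the mature one only. Cd40lg was among the leading genes of the immature cluster. Of the others in the set, Ccr9, Ckb, Nrgn and Asb2 were higher in cKO recirculating-Treg-like cells, and Chl1, Slc16a10, Nedd4 and F13a1 lower. RNA or cells of the immature cluster were not tested separately and stay open. RNA or cells of other classes, such as innate-like T-like cells, were not tested for. A biological cause in the recirculating-Treg-like cells stays open and was not tested.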

How the results depend on the processing

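Chosen only after the results were seen were the alternatives with equal cells per cluster, without low-UMI clusters, with Treg-like cells only or as the denominator, and the lists and interaction without single libraries. In a fit without 1 library the lone library of its group is assumed to vary like the others. P-values with the replicate block rest largely on the spread pooled across genes, since few residual degrees of freedom are left per gene.

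The number of genes called in Treg-like cells (4) was 1470 with the replicate block, 300 with DESeq2, 82 without the filter on low counts, 12 with equal cells per cluster and 560 with equal cells and the block, and 2 to 130 without single libraries. In recirculating-Treg-like cells (12) it was 98 with the block, 33 with DESeq2, 214 without the filter, 23 in the clustering without called genes, 23 with equal cells and 54 with equal cells and the block, and 2 to 157 without single libraries. In developing-Treg-like cells (5) it was 543 with the block, 18 with DESeq2, 105 without the filter, 10 with equal cells and 267 with equal cells and the block, and 10 to 18 without single libraries. In all cells (300) it was 2075 with the block, 1141 with DESeq2, 788 without the filter, 196 with doublets kept and 4 in Treg-like cells only, and 36 to 1251 without single libraries. The interaction (81 genes) gave 366 with the block and 104 to 234 without single libraries. Among the genes, class shares and list tests printed, the replicate block changed no other call than those given with its value. The cause of these differences was not tested.

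Ikzf4 passed with DESeq2 in recirculating-Treg-like cells (-1.60) and in all cells (-1.11). Without single libraries its log2 change ran from -1.26 to -0.55 in Treg-like, -1.92 to -1.19 in recirculating-Treg-like, -1.03 to -0.37 in developing-Treg-like and -1.42 to -0.70 in all cells. The number of class shares called (6) was 3 at Leiden resolution 0.5, 0 with Treg-like cells as the denominator and 0 to 8 without single libraries. The recirculating share was at -0.75 with that denominator and -1.10 to -0.82 without single libraries. Lists called numbered 0, 0 and 0 with an estimated correlation and 0, 0 and 0 with fry for a shared direction (1, 1 and 0 with the replicate block, and 15, 0 and 1 for either direction), against 17, 10 and 5 in Treg-like, recirculating-Treg-like and developing-Treg-like cells. With the replicate block 11 lists passed in developing-Treg-like cells, and without single libraries 6 to 14 in recirculating-Treg-like and 6 to 10 in developing-Treg-like cells.

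Signs turned for Maf (0.0823 and 0.0768), Pdcd1 (0.0308 and 0.0288), Nt5e (0.0228 and 0.0226) and Cxcr6 (0.0692 and 0.0683) in Treg-like cells with equal cells per cluster, without and with the replicate block. They turned for C1qc (0.12) and C1qb (0.0874) in Treg-like cells only. The share of developing-Treg-like cells, at -0.24 to 0.25 without single libraries, turned without cKO 1 (-0.24), without WT 2 (-0.11), with doublets kept (-0.0294) and without low-UMI clusters (-0.0102). The cause was not tested. Of 1208 values of 89 named results on genes, 979 kept direction and side of the threshold, 132 newly passed, 87 no longer passed and 10 turned. Of 73 values of 6 class shares the counts were 57, 2, 10 and 4. In the tests within a class and in all cells the smallest simulated changes were recovered in 24 to 58% of genes, and in the interaction test in 20%.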

Other observations

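The gene tests and the replicate block were set before the data were examined, and the fit with equal cells per cluster and the choice of clusters and genes printed came after their values were seen. Further named genes of Treg-like cells did not pass in edgeR with n = 2 libraries per genotype, and passed with batch as a block. Lower in cKO were the integrin gene Itgae (59.9 to 41.2 CPM, log2 -0.54, SE 0.07, adjusted p = 0.158, blocked 5.64e-06), the chemokine receptor genes Ccr4 (log2 -0.63, SE 0.08, adjusted p = 0.116, blocked 5.09e-05) and Cxcr6 (log2 -0.81, SE 0.11, adjusted p = 0.162, blocked 0.00282), and the transcription factor gene Maf (31.7 to 21.3 CPM, log2 -0.57, SE 0.06, adjusted p = 0.104, blocked 0.00243). Nrp1, Pdcd1, Nt5e, Relb, Cd74 and Tox2 were lower too (log2 -0.33, -0.24, -0.19, -0.15, -0.53 and -0.77, adjusted p = 0.177, 0.197, 0.197, 0.332, 0.197 and 0.104, blocked 6.40e-05, 0.000431, 0.00105, 0.00442, 1.66e-05 and 0.000303). The survival gene Bcl2 and the conventional T cell genes Actn1 and Pde3b were higher (log2 0.24, 0.17 and 0.23, adjusted p = 0.197, 0.264 and 0.292, blocked 0.000832, 0.00266 and 0.00185). With equal cells per cluster most of these changes were smaller or turned: the log2 change was -0.0388 for Itgae in Treg-like cells, 0.0692 for Cxcr6 in Treg-like cells, 0.0823 for Maf in Treg-like cells, -0.0818 for Tox2 in Treg-like cells and -0.15 for Ccr4 in Treg-like cells, while Cd74 in Treg-like cells passed there (-0.33, adjusted p = 0.0330). Over the alternatives with all libraries the lowest adjusted p of these genes ran from 6.74e-13 for Cd74 to 0.00442 for Relb, and the highest from 0.409 for Cd74 to 0.999 for Itgae and others. The recirculating-Treg-like share of these cells was lower in the same cKO libraries.

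In recirculating-Treg-like cells the cytokine feedback gene Socs2 and the transcription factor gene Sox4 were higher (log2 0.28 and 0.32, adjusted p = 0.196 and 0.209, blocked 0.0350 and 0.0396). S100a11 and Crip1 were lower there (log2 -0.21 and -0.22, adjusted p = 0.428 and 0.556, blocked 0.0487 and 0.0371). In developing-Treg-like cells Il2rb, a chain of the interleukin 2 receptor, Lta, which encodes lymphotoxin, and Vim, which encodes vimentin, were higher (log2 0.13, 0.15 and 0.14, adjusted p = 0.789, 0.935 and 0.832, blocked 1.60e-06, 1.99e-07 and 1.15e-06). With equal cells per cluster these were at 0.0453 for Il2rb in developing-Treg-like cells, 0.0455 for Lta in developing-Treg-like cells and 0.0735 for Vim in developing-Treg-like cells, and at Leiden resolution 0.5 they were at 0.0439, 0.0668 and 0.0204. Over the alternatives with all libraries the highest adjusted p ran from 0.492 for Socs2 to 0.978 for Sox4 in the first of these classes and was 0.9998 or more for the 3 genes of developing-Treg-like cells.

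The clusters that were not recirculating showed further Treg states. A cluster led by the immediate early genes Nr4a1, Nr4a3, Egr1 and Egr2, which respond to T cell receptor signals, made up 4.09, 4.29, 2.88 and 2.89% of WT 1, cKO 1, WT 2 and cKO 2. A cluster led by the replication genes Mcm3, Mcm5 and Hells made up 2.65, 2.80, 2.97 and 3.19% in that order. Interferon-responding Treg-like cells, led by Ifit3, Ifit1 and Rsad2, made up 4.73, 4.79, 4.80 and 4.14%.

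Foxp3 was at 504 CPM in the developing-Treg-like cluster led by Lta, Gpr83 and Il2ra, and at 6.89 CPM in the mature CD4 SP-like and 2.32 CPM in the immature SP-like cluster. Ikzf4 was at 18.6 and 14.1 CPM in those SP-like clusters. Xist was at 513, 536, 539 and 565 CPM in WT 1, cKO 1, WT 2 and cKO 2, and the Y-linked gene Ddx3y had 2, 1, 2 and 0 UMIs in all kept cells.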
